A study of Oryza sativa and Arabidopsis thaliana with 24 samples.

How the data were processed

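The data were 24 tRNA-seq libraries in 12 groups with 2 replicates each. Arabidopsis gave 5 tissues (flower, silique, rosette leaf, stem leaf and stem) grown at 23 °C, and rice gave shoot and root of control, cold-treated (4 °C for 8 h) and salt-treated (300 mM NaCl for 8 h) seedlings, and panicle. For each species 3 abundance tables were used: reads per tRNA (called tRNA signal here), tRF reads summed per tRNA (tRF totals), and single fragment sequences (individual tRFs) with their class, which is tRF-5, tRF-3, 5'-halves or 3'-halves. The values were on a log2 scale of reads scaled to library size (RPM), per the file headers, and were turned back to RPM before any mean was taken. The headers give log2 of 1 plus the RPM, but the values of the tables per tRNA fitted whole reads in full only with 0.5 added, and those of the individual tRFs fitted with 1 added. The 4 silique and stem libraries of tRNA signal barely tell the offsets apart, since 96.8% to 98.6% of their values were whole with the other offset too (at most 62.6% in all other libraries). With these offsets, 100% of the values in every library were whole multiples of a single read (within 0.05 of a whole number), so read numbers could be recovered for counting error and for floors. Adapters were removed by the authors with cutadapt and TAIR10 is the only genome build named; versions, aligner, read length limits and the handling of reads shared by several tRNAs are not given in the sources used here. The rice build and the total by which the tRNA signal and the rice tRF values were scaled are also not given in the sources used here.

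Before the data were examined, the plan allowed for count tables or normalized values, and since the values were log2 RPM, the plan for normalized values applied. Each comparison was then a limma fit (trend) on log2(RPM + 1) with 1 mean per group and a spread shared by all groups of the species, for features with a mean of at least 1 RPM. Features with identical values in all libraries were joined. A feature was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each comparison. The comparisons were any difference among the 5 Arabidopsis tissues, flower and silique against rosette leaf, stem leaf and stem, rice root against shoot in control seedlings, panicle against the mean of control shoot and root, cold and salt against control in each organ, and the difference of each stress effect between the organs. Shares of the signal by origin, fragment class and length were tested by exact permutation of libraries, two-sided: 945 partitions of the 10 Arabidopsis libraries, and 924 splits of 6 root and 6 shoot libraries of rice. Each library counted as an independent unit, and the rice splits did not keep treatments or replicate pairs together. With whole groups as units, too few splits of rice exist for a p under 0.05. Within 1 rice organ a stress against control allows 6 arrangements (smallest possible p 0.333), and both organs together allow 36 (smallest possible p 0.0556), so no share could pass 0.05 for a stress. Class and length shares are shares of the reads of the listed individual tRFs.

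Lists fixed before the data were examined were tRNAs by origin (nuclear, plastid, mitochondrial), each amino acid family of nuclear tRNAs, fragment classes, plastid Glu-TTC, and fragments often described in plants (nuclear Ala-AGC, Arg-CCT, Arg-TCG, Asp-GTC, Glu-CTC, Gly-GCC, Gly-TCC, His-GTG and Trp-CCA). Lists with at least 3 tested features were tested with limma's camera at a preset correlation of 0.01, and with an estimated correlation. Of 426 list tests over 21 comparisons, 84 were called with the preset and 47 with the estimated correlation, 43 of them with both. Counts within a list are those of the whole comparison, and counts adjusted over the list alone are given where they differ. Every list printed in the text carries both values, and those with an adjusted p under 0.05 for both hold in either case. A second set of lists, without nuclear copies that resemble organelle tRNAs, was added after the data had been seen and was adjusted separately. Named features follow a rule fixed before the data were examined: among called features with a mean of at least 10 RPM and no overlap between the libraries of the groups, the 6 largest folds in each direction (12 widest ranges for the test over 5 tissues), the 5 most abundant features of each species and level, and the most abundant member of each fixed list. Features named outside this rule, which are the amino acid family shares and those of the closing parts, were chosen after the values had been seen. Folds between group means are ratios of mean RPM. Shares of the tRNA signal beside them were added after the values had been seen and were not tested. The log2 folds come from the fit, and on the log2(RPM + 1) scale they understate the change of features with low values. Where a group had no reads, a floor of 3 reads in its shallower library was used and the fold is given as "at least". Floors and intervals of this kind cover counting error only.

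Rice tRNAs were classed by the loci in the deposited tables. All 25 plastid tRNAs of rice also had nuclear loci, so their reads cannot be assigned to a single genome, and the same holds for 9 of 15 mitochondrial tRNAs. Of 259 nuclear rice tRNAs, 61 lay within 15 edits of an organelle tRNA and are called plastid-like or mitochondrial-like, 48 of them within 3 edits. This class was added after the values had been seen, and in the shares these tRNAs count as nuclear unless stated. Coordinates are printed as deposited, with the first locus of tRNAs that have several. For Arabidopsis, the reference sequence at hand was compared with the deposited tRNAs: 514 of 598 nuclear loci had the identical sequence and 77 more did after an intron was removed, and all 598 lay in annotated tRNA genes. For plastid loci these numbers were 29, 8 and 36 of 37, whereas 0 of 23 mitochondrial loci matched, so mitochondrial coordinates are not comparable with that reference.

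The replicates may be technical: the scaling totals of replicate 2 over replicate 1 had a ratio of 1.57 to 1.62 over the 12 groups in the tRF tables and 1.41 to 1.503 in the tRNA tables. The p-values therefore measure only the spread between these samples, and may not extend to other plants. Replicates with the same number also resembled each other across groups at the level of individual tRFs, where all 10 Arabidopsis and all 21 rice pairs of groups had a correlation above 0.1 (median 0.196 and 0.287). A replicate block as a covariate changed the number of calls by a factor of 0.968 to 1.08 over 24 counts. Rescaling to a median log ratio of 0 was also run, and its counts are given beside the main ones where the balance of higher and lower features depends on it. Simulated data used the read depths of these libraries, with a variance of 3 times counting error for every feature. Each simulated set had 40 changed tRNAs or tRF totals, or 200 changed individual tRFs. There, 4.55% of the called Arabidopsis tRF totals and 6.26% of those in cold rice root were false, against 3.54% and 1.63% for individual tRFs and 32.5% and 17.9% for tRNA signal. The real spread varied more: the most abundant rice tRF totals had a mean chi-square per degree of freedom of 1.76 to 9.20 over the groups. Counts of tRNA signal may therefore hold more false calls than the 5% set, but the false share depends on how many features changed, which is not known for the real data. At a true 4-fold change, 93.2% and 96.5% of tRF totals were recovered, 44.2% and 81.6% of individual tRFs, and 51.2% and 67.8% of tRNA signal values. The tRF-to-tRNA ratio is not analysed here because the tables are not scaled alike. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and edlib 1.3.9, and R 4.3.3 with limma 3.58.1 were used.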

Results

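The libraries measured tRNAs and tRNA-derived fragments (tRFs) in 5 Arabidopsis tissues and in 7 rice groups, with n = 2 libraries per group. Arabidopsis libraries held 19741 to 232097 reads of tRNA signal and 259630 to 1536470 tRF reads, and rice libraries 20674 to 150441 and 130822 to 880814. Of the tRF reads, 159832 to 1293518 per Arabidopsis library and 67985 to 434778 per rice library belonged to individually listed fragments (5826 and 2794 sequences). Values are mean ± SD over 2 libraries, in scaled reads (RPM) or percent.

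Leaves held the largest plastid share of the Arabidopsis tRNA signal, 71.3 ± 0.199% in rosette leaf and 71.4 ± 0.0167% in stem leaf (n = 2 each). The share was 47.8 ± 0.453% in stem, 33.6 ± 0.0348% in flower and 32.2 ± 0.493% in silique. Among tRFs it was lower in every tissue: 31.5 ± 0.0608% in stem leaf, 31.2 ± 0.0355% in rosette leaf, 21.5 ± 0.0235% in stem, 12.1 ± 0.0311% in flower and 10.6 ± 0.148% in silique. Mitochondrial tRNAs had their largest share in flower, with 4.84 ± 0.0473% of the tRNA signal against 2.06 ± 0.1503% in silique and 1.33 ± 0.0249% in stem leaf. The plastid shares differed among the 5 tissues for the tRNA signal (exact permutation p = 0.00212, adjusted p = 0.00244) and for tRFs (p = 0.00106, the smallest possible, adjusted p = 0.00159). The mitochondrial share of the tRF signal differed least, by 0.166 percentage points (exact permutation, adjusted p = 0.0317).

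Fragments from the 5' end made up most of the listed Arabidopsis tRFs in every tissue. The tRF-5 class ranged from 52.8 ± 0.623% in stem leaf to 61.5 ± 0.218% in silique and 63.1 ± 0.636% in stem (n = 2 each). The 5'-halves ranged from 23.0 ± 0.118% in silique to 38.0 ± 0.592% in stem leaf. The tRF-3 class was largest in silique at 10.6 ± 0.108% and rosette leaf at 9.41 ± 0.157%, and smallest in stem at 3.45 ± 0.0304%. Stem held the most fragments of 21 to 23 nt, 17.6 ± 0.230% against 5.30 ± 0.0522% in flower. The stem value comes largely from a single nuclear Ser-AGA tRF-5 of 23 nt, named below, and no share was computed without it. The nuclear Ser-AGA family gave 13.5 ± 0.139% of the whole tRF signal in stem and 3.36 ± 0.0459% in flower. Flower held the most fragments of 28 nt and longer, 72.3 ± 0.307% against 49.7 ± 0.548% in stem. All 9 class and length shares differed among the tissues (exact permutation, adjusted p from 0.00159 to 0.00244), and 3'-halves stayed within 1.92 percentage points. The listed tRFs held 159832 of 267549 tRF reads in silique replicate 1, but 397859 of 445684 in stem leaf replicate 1. These shares therefore cover unlike parts of the tRF signal.

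Single nuclear Arg, Gln and Cys tRNAs gave a much larger part of the tRF reads in silique than in leaves. The tRF totals of each Arabidopsis library summed to 1000000 RPM, against 105504 to 146214 RPM in rice libraries. The Arabidopsis values are thus parts of the tRF reads and do not show how many tRFs a tissue held. Arg-TCT at_tR28 (chromosome 2, 18569911 to 18569983) reached 12069.9 ± 61.9 RPM in silique against 344 ± 51.8 RPM in stem leaf (35.1-fold, n = 2 each). Gln-CTG at_tR67 had 21651 ± 88.1 RPM in silique and 759 ± 1.70 RPM in rosette leaf (28.5-fold), and Cys-GCA at_tR53 4064 ± 88.2 and 148 ± 5.98 RPM (27.4-fold). Plastid Met-CAT at_tR135 (plastid genome, 52056 to 52128) showed the reverse, with 1929 ± 186 RPM in stem leaf against 40.5 ± 16.8 RPM in silique (47.7-fold). Mitochondrial Met-CAT at_tR136 had 237 ± 29.5 RPM in rosette leaf and no reads in silique (at least 21.1-fold). The most abundant tRFs came from nuclear Glu-TTC at_tR77, with 236109 ± 767 RPM in flower and 133106 ± 1284 RPM in stem. Nuclear Gly-TCC at_tR92 followed with 216072 ± 1241 RPM in flower and 119297 ± 548 RPM in silique. By family, nuclear Ser-AGA gave 13.5 ± 0.139% of the tRF signal in stem and 2.40 ± 0.0384% in rosette leaf, and nuclear Gln-CTG 12.8 ± 0.00147% in silique and 2.50 ± 0.0298% in stem leaf. Of 226 tRF totals, 213 differed among the 5 tissues (limma adjusted p = 8.0e-14 for at_tR28 and 5.5e-16 for at_tR67).

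Flower and silique together had lower plastid tRFs than the vegetative tissues. The 6 largest falls in tRF totals were all plastid, led by Met-CAT at_tR135 (log2 fold -3.34), Leu-CAA at_tR114 (-3.01) and Tyr-GTA at_tR219 (-2.52). Leu-CAA at_tR114 had 346 ± 29.4 RPM in silique and 8501 ± 427 RPM in stem leaf (n = 2 each). The largest rises were in nuclear Ser-AGA at_tR159 (3.68), nuclear Cys-GCA at_tR55 (3.21) and mitochondrial Gly-GCC at_tR91 (2.70). Nuclear Trp-CCA at_tR203 had 1600.5 ± 57.1 RPM in silique and 91.5 ± 28.6 RPM in stem. At a limma adjusted p under 0.05, 121 of 226 tRF totals were higher and 53 lower (median log2 fold 0.53, and 90 and 75 after rescaling), of which 75 and 20 had a fold of at least 2 (44 and 35 after rescaling). Of 30 plastid totals, 1 was higher and 27 lower (limma camera adjusted p = 1.9e-17, and 0.00265 with an estimated correlation). Of 177 nuclear totals, 114 were higher and 24 lower (85 and 41 after rescaling, limma camera adjusted p = 2.2e-11, and 0.00944 with an estimated correlation). Among 8 nuclear Ala totals, 0 were higher and 8 lower (limma camera adjusted p = 7.7e-05, but adjusted p = 0.260 with an estimated correlation). By family, nuclear Ala-AGC had 89631 ± 2369 RPM in stem, 40652 ± 746 RPM in stem leaf and 22069 ± 198 RPM in rosette leaf. Silique had 35638 ± 1549 RPM and flower 23933 ± 321 RPM of this family, so its fall rests largely on stem and does not hold against rosette leaf. For nuclear Gln, of 7 totals, 7 were higher and 0 lower (limma camera adjusted p = 0.00662, but adjusted p = 0.163 with an estimated correlation). The nuclear Gln-CTG family had 128362 ± 14.7 RPM in silique and 48027 ± 393 RPM in flower. It had 48429 ± 552 RPM in stem, 27216 ± 306 RPM in rosette leaf and 25042 ± 298 RPM in stem leaf, so flower did not exceed stem.

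The tRNA signal of Arabidopsis summed to 849094 ± 1836 RPM in silique and 166037 ± 8072 RPM in rosette leaf. It summed to 322140 ± 12118 RPM in flower, 332640 ± 8317 RPM in stem leaf and 508473 ± 1643 RPM in stem. RPM folds between tissues include these differences, and shares of the tRNA signal are given beside them. Nuclear Leu-CAA at_tR113 had 31284 ± 14.5 RPM in silique and 229 ± 94.6 RPM in rosette leaf (137-fold, n = 2 each), which is 3.68 ± 0.00968% and 0.137 ± 0.0503% of the signal (26.9-fold). Nuclear Glu-TTC at_tR77 had 113663 ± 278 and 5163 ± 183 RPM in the same tissues (22.0-fold), or 13.4 ± 0.0617% and 3.11 ± 0.0408% of the signal. Plastid Gly-TCC at_tR93 was lowest in silique (43.1 ± 60.9 RPM) and highest in stem leaf (3167 ± 83.2 RPM), or 0.00507 ± 0.00716% and 0.952 ± 0.00121% of the signal. Its silique value rests on very few reads, since 1 read equals 43.1 RPM in silique replicate 1 and 28.7 RPM in replicate 2. Plastid Glu-TTC at_tR80 did not follow at_tR93, with 75601 ± 0.382 RPM in silique against 4988 ± 372 RPM in rosette leaf, or 8.90 ± 0.0192% and 3.00 ± 0.0781% of the signal. The limma fit called 126 of 200 tRNAs different among the tissues at an adjusted p under 0.05, and 107 higher and 17 lower in reproductive tissue. The median log2 fold was 1.499, and 25 were higher and 34 lower after rescaling, so the balance of directions depends on the scaling. Flower had a lower total than stem leaf and stem. Flower and silique were not compared with the vegetative tissues one at a time, so these calls need not hold in flower. Of 30 plastid tRNAs, 6 were higher and 15 lower (0 and 27 after rescaling, limma camera adjusted p = 2.4e-11, but adjusted p = 0.0571 with an estimated correlation). Among 7 nuclear Gln tRNAs, 7 were higher and 0 lower (limma camera adjusted p = 0.00212, but adjusted p = 0.191 with an estimated correlation). For nuclear Glu, of 8 tRNAs, 8 were higher and 0 lower (limma camera adjusted p = 0.00656, but adjusted p = 0.191 with an estimated correlation).

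Single fragments also differed among the tissues. The plastid Leu-CAA tRF-5 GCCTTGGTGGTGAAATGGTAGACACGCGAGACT had 475 ± 1.43 RPM in rosette leaf and no reads in silique (at least 42.4-fold, n = 2 each). The plastid Val-TAC 5'-half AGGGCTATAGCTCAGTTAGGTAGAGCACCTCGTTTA had 1989 ± 25.6 and 6.12 ± 1.92 RPM in the same tissues (325-fold). The nuclear Ser-AGA tRF-5 GTGGACGTGCCGGAGTGGTTATC of 23 nt reached 119625 ± 2305 RPM in stem against 14465 ± 62.2 RPM in rosette leaf (8.27-fold). The nuclear Gly-TCC 5'-half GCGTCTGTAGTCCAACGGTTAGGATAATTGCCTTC had 51682 ± 130.2 RPM in stem leaf and 1999.8 ± 89.6 RPM in silique (25.8-fold). Of 5808 individual tRFs, limma called 1931 different among the 5 tissues at an adjusted p under 0.05 (1248 without flower replicate 1).

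In rice, plastid tRNAs made up 49.8 ± 0.0450% of the tRNA signal in control shoot, 19.4 ± 0.109% in panicle and 3.43 ± 0.102% in control root (n = 2 each). Among tRFs the plastid shares were 27.4 ± 0.327%, 11.9 ± 0.0782% and 2.12 ± 0.0441%. Cold-treated shoot had 42.0 ± 0.796% of tRNA signal and 21.8 ± 0.412% of tRFs from plastid tRNAs, and salt-treated shoot 46.1 ± 0.397% and 15.1 ± 0.00490%. Cold-treated root had 11.1 ± 0.407% and 3.57 ± 0.0272%, and salt-treated root 5.93 ± 0.341% and 1.70 ± 0.00804%. With plastid-like nuclear copies counted as plastid, the tRF shares were 40.3 ± 0.450% in control shoot, 31.7 ± 0.528% in cold-treated shoot, 24.6 ± 0.0623% in salt-treated shoot and 18.8 ± 0.115% in panicle. In root they were 2.83 ± 0.0665% in control, 5.32 ± 0.0246% under cold and 2.39 ± 0.0145% under salt. Over 6 root and 6 shoot libraries the plastid share was lower in root by 39.1 percentage points of tRNA signal and 18.98 of tRFs (exact permutation p = 0.00216, the smallest possible, adjusted p = 0.00361). As in all tests of shares between root and shoot, each library counted as an independent unit, although replicates may be technical. The mitochondrial share of tRNA signal was 0.149 points higher in root (exact permutation, adjusted p = 0.0325), but 0.0723 points (exact permutation p = 0.377) when organelle-like nuclear copies were counted with the organelle. That of tRFs did not pass (0.718 points, exact permutation p = 0.0411, adjusted p = 0.0514). Within an organ no stress could pass: the plastid share of tRFs in root differed by 1.45 points under cold (exact permutation p = 0.333, the smallest possible).

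**Figure D1:**
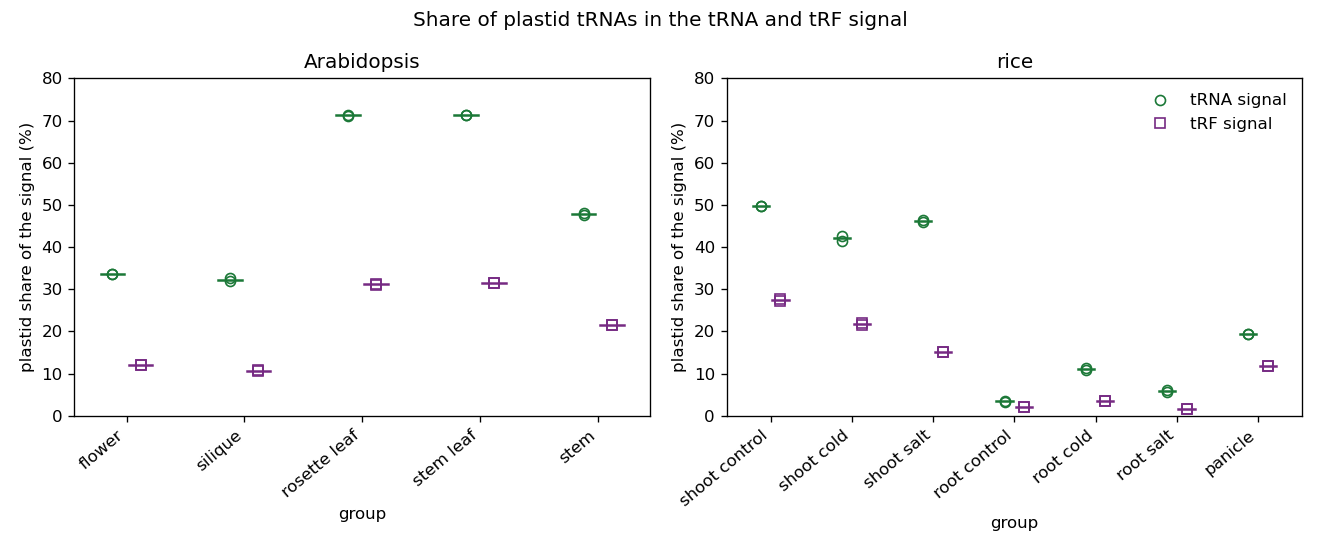
Plastid share (percent of the RPM signal) of tRNAs and of tRFs in each Arabidopsis and rice group, with single libraries as points and horizontal lines at the mean of n = 2. Plastid tRNAs give 71.4% of the tRNA signal in stem leaf, 49.8% in control shoot and 3.43% in control root.

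Rice root and shoot differed in fragment classes among the listed tRFs. These held 165940 of 358133 tRF reads in control root replicate 1, 138101 of 253790 in control shoot replicate 1 and 266195 of 422228 in panicle replicate 1. The 3'-halves made up 30.4 ± 0.503% of listed tRFs in control root and 11.7 ± 0.348% in control shoot (n = 2 each). The tRF-3 class made up 10.6 ± 0.0387% in control root and 24.8 ± 0.206% in control shoot, and 12.8 ± 0.157% in salt-treated shoot. The 5'-halves were lowest in control root at 13.8 ± 0.0659% and highest in panicle at 31.0 ± 0.289%. In root, 3'-halves stood at 21.5 ± 0.632% under cold and 25.1 ± 0.437% under salt. Root minus shoot was 15.1 percentage points for 3'-halves, -11.04 for tRF-3, 6.12 for 18 to 20 nt, -2.93 for 21 to 23 nt and -0.645 for 15 to 17 nt (exact permutation p = 0.00216 each, adjusted p = 0.00361). Fragments of 24 to 27 nt were lower in root by 2.14 points (exact permutation, adjusted p = 0.0325). No difference passed for tRF-5 (exact permutation p = 0.994), 28 nt and longer (p = 0.801) or 5'-halves (-4.11 points, adjusted p = 0.0574). Among fragments without a mismatch, tRF-5 was higher in root by 5.51 points (exact permutation p = 0.0173, unadjusted), and 15 to 17 nt no longer passed (-0.214 points, exact permutation p = 0.279).

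**Figure D2:**
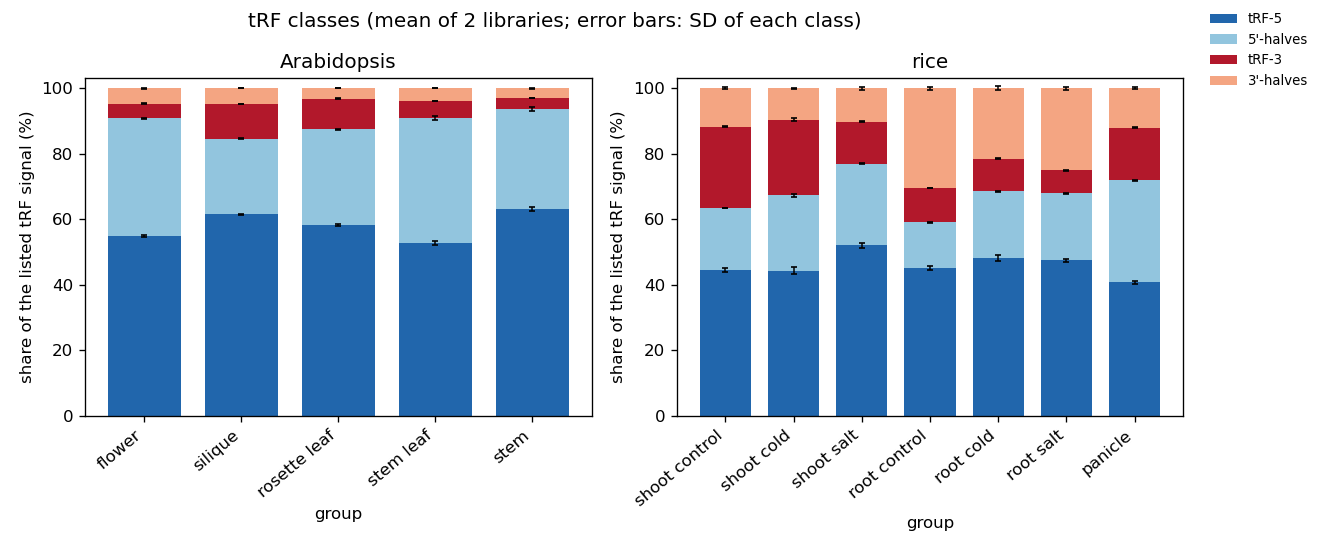
Share of listed tRF reads (percent) by fragment class in each group, stacked, as the mean of n = 2 libraries with the SD of each class as error bars. Control root has the largest 3'-half share (30.4%) and control shoot the largest tRF-3 share (24.8%).

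Nuclear Glu-CTC tRFs marked the rice root. Glu-CTC os_tR92 (chromosome 1, 35798452 to 35798524) had 4796 ± 54.8 RPM in control root and 468 ± 7.90 RPM in control shoot (10.3-fold, n = 2 each), and os_tR96 4792 ± 34.6 and 622 ± 30.8 RPM. The nuclear Glu-CTC family held 28.4 ± 0.324% of the tRF signal in control root and 10.7 ± 0.179% in control shoot. Plastid-like Gly-GCC os_tR116 had 468 ± 31.9 RPM in shoot and 6.70 ± 0.714 RPM in root (69.9-fold lower). Plastid Tyr-GTA os_tR277, among the 5 most abundant, had 7851 ± 210.3 and 487 ± 3.48 RPM. Of 272 tRF totals, limma called 116 higher and 108 lower in root (adjusted p = 3.1e-23 for os_tR92 and 3.5e-17 for os_tR116). Of 24 plastid totals, 0 were higher and 23 lower (limma camera adjusted p = 2.8e-10, and 0.00257 with an estimated correlation). Among 16 nuclear Glu totals, 14 were higher and 1 lower (limma camera adjusted p = 1.1e-04, and 0.0172 with an estimated correlation). For nuclear Arg, of 23 totals, 15 were higher and 5 lower (limma camera adjusted p = 0.0495, but adjusted p = 0.159 with an estimated correlation).

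In the tRNA signal, nuclear Ile-AAT os_tR138 had 619 ± 34.7 RPM in shoot and 12666 ± 100.4 RPM in root (20.47-fold, n = 2 each). The signal summed to 46826 ± 1453 RPM in shoot and 178933 ± 6420 RPM in root, and as shares of it os_tR138 had 1.32 ± 0.0331% and 7.08 ± 0.310% (5.36-fold). Lys-CTT os_tR163 had 955 ± 72.1 and 16472 ± 1161 RPM (17.2-fold, or 2.04 ± 0.0907% and 9.20 ± 0.319% of the signal), and Ser-AGA os_tR229 no reads in shoot and 85.3 ± 5.89 RPM in root (at least 23.1-fold). Plastid Asp-GTC os_tR55 was lower in root, 998 ± 107 against 3897 ± 28.5 RPM, or 0.557 ± 0.0395% against 8.33 ± 0.198% of the signal. The limma fit called 144 of 244 tRNAs higher and 37 lower in root at an adjusted p under 0.05 (median log2 fold 2.12, and 70 and 72 after rescaling). Of 23 plastid tRNAs, 0 were higher and 18 lower (limma camera adjusted p = 1.4e-16, and 0.0116 with an estimated correlation).

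Among individual rice tRFs, the nuclear Glu-CTC 3'-half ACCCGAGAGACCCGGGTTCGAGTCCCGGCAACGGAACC had 14.6 ± 1.19 RPM in control shoot and 292 ± 3.26 RPM in control root (n = 2 each). The plastid Gly-GCC 5'-half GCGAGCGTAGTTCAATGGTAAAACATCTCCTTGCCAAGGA had 158 ± 1.46 RPM in shoot and no reads in root (at least 154-fold lower). The plastid Tyr-GTA tRF-3 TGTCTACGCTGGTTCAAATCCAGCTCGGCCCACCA had 3260.4 ± 83.6 and 216 ± 8.88 RPM. Of 2794, limma called 613 higher and 769 lower in root at an adjusted p under 0.05 (median log2 fold -0.22, and 764 and 640 after rescaling). With a mean of at least 10 RPM, 606 of 806 differed (306 higher, 300 lower). Of 844 3'-halves, 358 were higher and 94 lower (362 and 97 adjusted over the list alone, limma camera adjusted p = 2.3e-13, and 7.1e-07 with an estimated correlation). Of 878 tRF-3 fragments, 69 were higher and 347 lower (69 and 344 adjusted over the list alone, limma camera adjusted p = 2.9e-07, and 2.3e-05 with an estimated correlation). Of 113 mitochondrial fragments, 33 were higher and 14 lower (limma camera adjusted p = 0.0312, and 0.0373 with an estimated correlation). Of 47 plastid Glu-TTC fragments, 0 were higher and 39 lower (1 and 40 adjusted over the list alone, limma camera adjusted p = 6.7e-11, and 3.9e-04 with an estimated correlation). Of 665 fragments often described in plants, 201 were higher and 98 lower (195 and 93 adjusted over the list alone, limma camera adjusted p = 1.4e-04, and 0.00655 with an estimated correlation).

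Among the tRF totals higher in panicle were a nuclear Ser-AGA and a nuclear Gln-CTG. Ser-AGA os_tR227 had 2259.6 ± 70.3 RPM in panicle, 367 ± 20.2 RPM in control shoot and 267 ± 7.44 RPM in control root (n = 2 each). Gln-CTG os_tR74 had 3571 ± 153, 695 ± 0.0760 and 585 ± 0.0746 RPM. Lower in panicle were nuclear Arg-TCT os_tR34 (log2 fold -1.46), nuclear Gly-TCC os_tR127 (-1.45) and mitochondrial Trp-CCA os_tR274 (-1.28). In the tRNA signal, plastid Leu-CAA os_tR149 reached 4650.5 ± 227 RPM against 734 ± 25.8 RPM in shoot and 207 ± 56.8 RPM in root, or 2.56 ± 0.0275%, 1.57 ± 0.00641% and 0.115 ± 0.0276% of the signal. At a limma adjusted p under 0.05, 165 tRF totals were higher and 43 lower than the mean of shoot and root (median log2 fold 0.44, and 92 and 96 after rescaling), of which 73 and 16 had a fold of at least 2 (35 and 32 after rescaling). Of tRNAs, 148 were higher and 1 lower (median 1.41, and 41 and 39 after rescaling). No list fixed before the data were examined was called in panicle.

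In cold-treated rice shoot, single nuclear tRNAs for Ser and Trp showed large rises in tRFs. Ser-AGA os_tR228 rose from 17.5 ± 2.86 to 111 ± 0.820 RPM (6.35-fold, n = 2 each), and Trp-CCA os_tR272 from 22.8 ± 2.34 to 100.7 ± 0.0282 RPM. Ser-GCT os_tR238 rose from 147 ± 15.7 to 467 ± 3.31 RPM in tRFs and from 169 ± 42.4 to 1371 ± 7.72 RPM in the tRNA signal (0.363 ± 0.102% and 1.87 ± 0.0937% of it). Its tRF-3 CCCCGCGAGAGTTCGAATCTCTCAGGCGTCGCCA rose from 27.2 ± 4.46 to 263 ± 9.43 RPM. Plastid-like Phe-GAA os_tR199 dropped from 2608 ± 37.1 to 797 ± 27.001 RPM (limma adjusted p = 1.3e-14). At a limma adjusted p under 0.05, 85 of 272 tRF totals were higher and 52 lower (56 and 66 after rescaling), of which 13 and 5 had a fold of at least 2. Of tRNAs, 89 were higher and 6 lower (median log2 fold 0.68, and 32 and 36 after rescaling), and of individual tRFs 279 higher and 143 lower (231 and 212 after rescaling, and 192 and 69 without control replicate 1). Of 16 nuclear Glu totals, 14 were higher and 0 lower (limma camera adjusted p = 3.1e-08, and 0.00654 with an estimated correlation). Of 24 plastid totals, 1 was higher and 10 lower (1 and 8 adjusted over the list alone, limma camera adjusted p = 0.00549, and 0.0464 with an estimated correlation). Of 278 5'-halves, 46 were higher and 1 lower (48 and 3 adjusted over the list alone, limma camera adjusted p = 5.8e-05, and 0.00531 with an estimated correlation).

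Cold-treated rice root gained plastid tRFs. Plastid Asp-GTC os_tR55 rose from 135 ± 9.42 to 439 ± 6.47 RPM (3.25-fold, n = 2 each), and plastid-like Gly-GCC os_tR116 from 6.70 ± 0.714 to 38.3 ± 5.43 RPM (5.72-fold). Plastid Glu-TTC os_tR102 rose in the tRNA signal, from 1004 ± 0.530 to 3949.9 ± 298 RPM (3.93-fold), or from 0.561 ± 0.0198% to 3.33 ± 0.111% of the signal. The plastid Asp-GTC tRF-5 GGGATTGTAGTTCAATTGGTC of 21 nt rose 8.00-fold, from 21.5 ± 5.60 to 172 ± 6.44 RPM. Nuclear Ala-CGC os_tR9 fell from 33.8 ± 2.18 to 3.82 ± 1.34 RPM. Nuclear Ile-AAT os_tR138 fell in the tRNA signal from 12666 ± 100.4 to 5452 ± 274 RPM, or from 7.08 ± 0.310% to 4.595 ± 0.0387% of the signal. The limma fit called 71 tRF totals higher and 80 lower (adjusted p = 7.4e-16 for os_tR55), and 36 higher and 3 lower with a fold of at least 2. Of tRNAs, 27 were higher and 59 lower (median log2 fold -0.29, and 42 and 22 after rescaling), and of individual tRFs 164 higher and 98 lower (132 and 141 after rescaling). This last count depends on the model: 199 were higher and 268 lower with only the compared libraries, 229 and 261 with voom on recovered reads (chosen after seeing the data), and 91 and 36 without cold replicate 1.

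Of 24 plastid tRF totals in cold root, 19 were higher and 1 lower (limma camera adjusted p = 6.3e-06, and 0.0157 with an estimated correlation). Beside them, 7 nuclear tRF totals that were at least 4-fold higher in cold shoot than in control root differed in cold root by a median log2 fold of 1.57. For the tRNA signal, of 23 plastid tRNAs, 13 were higher and 1 lower (limma camera adjusted p = 3.1e-08, but adjusted p = 0.0958 with an estimated correlation). Of 23 nuclear Arg totals, 4 were higher and 15 lower (5 and 15 adjusted over the list alone, limma camera adjusted p = 0.0173, but adjusted p = 0.107 with an estimated correlation). Among 844 individual 3'-halves, 10 were higher and 48 lower (8 and 43 adjusted over the list alone, limma camera adjusted p = 1.3e-09, and 6.9e-06 with an estimated correlation). Among 278 individual 5'-halves, 33 were higher and 5 lower (36 and 6 adjusted over the list alone, 24 and 8 after rescaling, limma camera adjusted p = 6.4e-04, and 0.00406 with an estimated correlation). Among 794 individual tRF-5 fragments, 89 were higher and 33 lower (107 and 39 adjusted over the list alone, limma camera adjusted p = 0.00824, and 0.0453 with an estimated correlation). Of 47 plastid Glu-TTC fragments, 15 were higher and 0 lower (19 and 1 adjusted over the list alone, limma camera adjusted p = 6.4e-08, and 0.00138 with an estimated correlation).

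Salt-treated rice shoot shared several gains with cold. Nuclear Trp-CCA os_tR272 rose from 22.8 ± 2.34 to 166 ± 13.0 RPM (7.28-fold, n = 2 each). Val-TAC os_tR299 rose from 120.05 ± 5.02 to 459 ± 22.7 RPM in tRFs and from 26.9 ± 0.287 to 228 ± 27.3 RPM in the tRNA signal. Plastid-like Phe-GAA os_tR199 fell from 2608 ± 37.1 to 912 ± 35.3 RPM, and plastid Asn-GTT os_tR37 in the tRNA signal from 545 ± 49.4 to 105 ± 14.5 RPM. The nuclear Glu-TTC 5'-half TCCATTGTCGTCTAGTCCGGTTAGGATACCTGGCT, among the 5 most abundant fragments, rose from 493 ± 6.69 RPM to 1562 ± 27.1 RPM under salt and 1200.2 ± 30.5 RPM under cold. In root it rose from 1444 ± 48.3 RPM to 3069 ± 36.5 and 2624 ± 7.98 RPM. At a limma adjusted p under 0.05, 109 tRF totals were higher and 59 lower (median log2 fold 0.18, and 71 and 121 after rescaling), of which 49 and 19 had a fold of at least 2 (10 and 50 after rescaling). Of tRNAs, 33 were higher and 32 lower, and of individual tRFs 487 higher and 386 lower (393 and 501 after rescaling, and 242 and 153 with only the compared libraries).

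Of 16 nuclear Glu totals in salt-treated shoot, 13 were higher and 1 lower (limma camera adjusted p = 4.8e-06, and 0.00754 with an estimated correlation). Of 24 plastid totals, 1 was higher and 15 lower (limma camera adjusted p = 1.4e-06, and 0.00657 with an estimated correlation). Among 9 nuclear Asp totals, 8 were higher and 0 lower (5 and 2 after rescaling, limma camera adjusted p = 0.0225, but adjusted p = 0.101 with an estimated correlation). For the tRNA signal, of 16 nuclear Ser tRNAs, 7 were higher and 0 lower (7 and 1 adjusted over the list alone, limma camera adjusted p = 7.5e-04, but adjusted p = 0.0647 with an estimated correlation). Of 278 5'-halves, 74 were higher and 13 lower (60 and 20 after rescaling, limma camera adjusted p = 1.1e-04, and 0.00215 with an estimated correlation). Of 878 tRF-3 fragments, 67 were higher and 162 lower (64 and 150 adjusted over the list alone, limma camera adjusted p = 1.4e-04, and 4.7e-04 with an estimated correlation).

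In salt-treated rice root, single nuclear Glu and His tRNAs gained tRFs, and nuclear Ser and mitochondrial ones were lower. Glu-TTC os_tR107 rose from 1438 ± 49.1 to 3419 ± 60.5 RPM (n = 2 each) and His-GTG os_tR130 from 1881 ± 68.2 to 3859 ± 85.4 RPM. The His-GTG 5'-half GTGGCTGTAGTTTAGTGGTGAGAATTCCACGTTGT rose 10.9-fold to 207 ± 2.28 RPM. Ser-AGA os_tR228 fell from 78.0 ± 0.220 to 12.1 ± 1.43 RPM and mitochondrial Tyr-GTA os_tR279 from 1698 ± 85.2 to 495 ± 22.1 RPM. In the tRNA signal, nuclear Leu-AAG os_tR147 fell from 785 ± 77.3 to 112 ± 18.9 RPM. The limma fit called 57 tRF totals higher and 97 lower at an adjusted p under 0.05 (76 and 73 after rescaling), of which 6 and 41 had a fold of at least 2 (10 and 27 after rescaling). Of tRNAs, 36 were higher and 30 lower, and of individual tRFs 138 higher and 158 lower. These 296 fragments became 166 to 195 when any of the 4 compared libraries was left out, 531 (222 higher, 309 lower) with only the compared libraries, and 465 (192 and 273) with voom on recovered reads (chosen after seeing the data). Of 17 nuclear Ser totals, 0 were higher and 15 lower (limma camera adjusted p = 1.7e-04, but adjusted p = 0.0846 with an estimated correlation). Of 14 mitochondrial totals, 0 were higher and 10 lower (limma camera adjusted p = 0.00898, but adjusted p = 0.148 with an estimated correlation). Of all 15 mitochondrial tRNAs of rice, 9 also have loci in another genome. Of 113 individual mitochondrial fragments, 0 were higher and 19 lower (0 and 25 adjusted over the list alone, limma camera adjusted p = 2.5e-05, and 0.00658 with an estimated correlation).

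**Figure D3:**
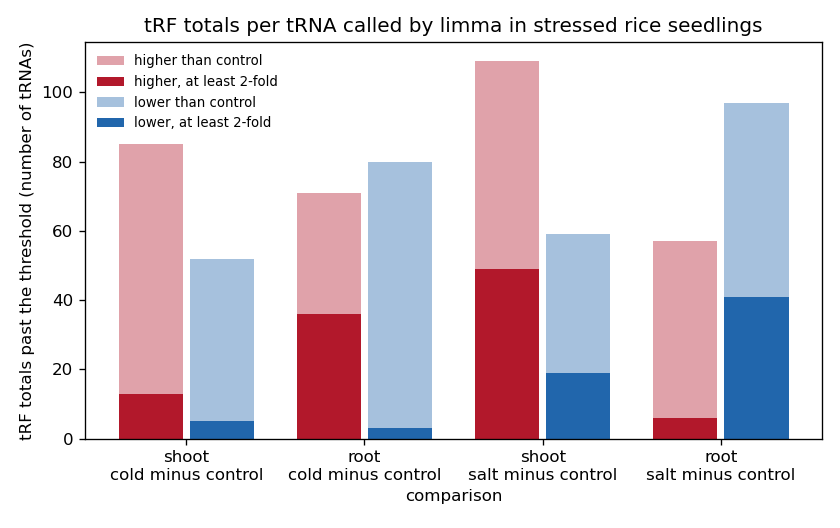
Number of tRF totals called higher or lower (limma adjusted p under 0.05, pale bars) and those of them with a fold of at least 2 (dark bars) for cold and salt in rice shoot and root, from n = 2 libraries per group, without error bars. For salt 109 are higher in shoot and 97 lower in root (71 and 73 after rescaling).

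Cold and salt shared called tRF totals, few of them with a fold of at least 2. In shoot, 69 of 272 were higher and 31 lower in both stresses, and 7 went in opposite directions (n = 2 libraries per group, limma adjusted p under 0.05 in each). In root, 28 were higher, 53 lower and 24 opposite. After rescaling, an alternative chosen after seeing the data, 44 were higher, 54 lower and 8 opposite in shoot, and 35, 32 and 24 in root, so the balance of directions depends on the scaling. With a fold of at least 2 in both stresses, the shared totals numbered 15 in shoot (11 higher, 4 lower) and 2 in root (2 higher, 0 lower). Independent calls would give 34.1 higher and 11.3 lower in shoot, and 14.9 and 28.5 in root (after rescaling, 14.6 and 29.4, and 19.8 and 19.9). Both stresses share the same 2 control libraries, and no fit with a separate control library for each stress was run. In 100 simulated draws of unchanged groups against shared controls the median overlap was 0 in both organs (highest 0 and 1). Unchanged groups give few calls by design, so this cannot show how many shared totals the controls add where real changes exist. The draws used the spread between replicates, which may be technical. The covariance of the log2 folds was 0.3597 in shoot and 0.230 in root, against 0.0278 and 0.0275 in the simulated draws, so part of the excess may come from the shared controls.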

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

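The tests of shoot tissue and of nuclear gene copies among the cold-treated roots were chosen before their results were seen, and the 3 tRNAs named per stress were chosen after their values were seen, as was the count of plastid-like ones among them.

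Cold acted differently on root and shoot tRFs. The limma interaction of organ and cold passed an adjusted p of 0.05 for 164 of 272 tRF totals, 66 higher and 98 lower in root relative to shoot (median log2 difference -0.16, and 78 and 76 after rescaling, n = 2 libraries per group). With a fold of at least 2 these were 42 and 28 (50 and 18 after rescaling). Of the 164, 53 passed in both organs in opposite directions: 20 were higher in cold root and lower in cold shoot, 15 of them plastid or plastid-like, and 33 the other way (25 and 21 after rescaling, chosen after seeing the data). The widest of the first kind came from Val-GAC. Plastid-like os_tR298 rose from 2.65 ± 0.128 to 11.1 ± 0.270 RPM in root and fell from 122 ± 3.46 to 67.7 ± 4.24 RPM in shoot (log2 difference 2.56, adjusted p = 2.6e-07). The differences were 2.37 for plastid os_tR295 (adjusted p = 6.8e-05) and 2.05 for plastid-like os_tR296 (adjusted p = 2.1e-05). Of 24 plastid totals, 21 were higher and 0 lower (limma camera adjusted p = 4.7e-09, and 0.00398 with an estimated correlation). Of 16 nuclear Glu totals, 1 was higher and 14 lower (limma camera adjusted p = 5.7e-05, and 0.0142 with an estimated correlation). The cold effect on the plastid share was larger in root than in shoot by 15.4 percentage points of tRNA signal and 7.07 of tRFs. This difference was noted because every root library moved up and every shoot library down, and it was not tested.

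Salt also separated the organs. The limma interaction of organ and salt passed for 172 of 272 tRF totals, 45 higher and 127 lower in root relative to shoot (median log2 difference -0.37, and 98 and 71 after rescaling, n = 2 libraries per group). With a fold of at least 2 these were 14 and 67 (53 and 21 after rescaling). Of 49 that passed in both organs in opposite directions, 45 were lower in root and higher in shoot, but only 18 of 51 after rescaling (chosen after seeing the data), where 33 went the other way, so the direction depends on the scaling. Nuclear Ser-AGA os_tR228 fell from 78.0 ± 0.220 to 12.1 ± 1.43 RPM in root and rose from 17.5 ± 2.86 to 46.7 ± 9.22 RPM in shoot (log2 difference -3.97, adjusted p = 2.7e-11). Nuclear Trp-CCA os_tR272 fell from 67.3 ± 12.5 to 39.8 ± 2.09 RPM in root and rose from 22.8 ± 2.34 to 166 ± 13.0 RPM in shoot (-3.55, adjusted p = 1.4e-10). Nuclear Gly-CCC os_tR113 had a difference of -3.42 (adjusted p = 8.6e-06). Of 16 nuclear Glu totals, 0 were higher and 13 lower (4 and 9 after rescaling, limma camera adjusted p = 0.00331, but adjusted p = 0.0582 with an estimated correlation). Of 17 nuclear Ser totals, 0 were higher and 14 lower (limma camera adjusted p = 0.0113, but adjusted p = 0.154 with an estimated correlation).

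The rise of plastid tRFs in cold root could reflect plastids of the root itself or shoot tissue among the sampled roots. A shoot portion of 8.62% would give the measured plastid share of tRFs, and it predicts a median log2 rise of 0.926 for the 7 nuclear tRF totals that were at least 4-fold higher in cold shoot than in control root. Their median rise was 1.57 (1.4996 to 2.27 over the 4 pairings of libraries), and 5 of 7 reached their predicted value. For the tRNA signal, 19.2% shoot would be needed, and 11 nuclear tRNAs had a median of 3.14 against 1.28 predicted. Both medians lay above the prediction, and tRFs and tRNA signal need different shoot portions. Since these features were picked by their level in cold shoot, tRNAs that rise under cold in both organs may be among them. The test thus cannot tell shoot tissue from a shared response to cold, and shoot tissue stays open. Plastid transcripts cannot be told apart from those of nuclear copies, since 0 rice plastid tRNAs lack a nuclear locus, and an effect of cold on root plastids was not tested separately.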

How the results depend on the processing

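Of 388 values of 57 main results under other settings, 348 held, 4 lost the threshold, 1 gained it and 35 moved. A share was judged by its direction and its side of the threshold, and 0 shares reversed with an exact permutation p under 0.05 in either setting. A count held if its total stayed within 1.5 times, and the balance of higher and lower features was not compared. Salt shoot tRF totals held in this sense, although 109 higher and 59 lower became 71 and 121 after rescaling. With each library left out in turn, 440 of 468 held, 13 lost the threshold, 15 moved and 0 shares reversed in that way. Named features held in 2972 of 3016 values, and in 1435 of 1532 with a library left out, with 0 reversed. A library left alone in its group is assumed to vary like the other groups. The replicate block changed no count by over 1.5 times. In simulated data with the depth of these libraries and a fixed spread, fewer 4-fold changes were recovered in tRNA signal and individual tRFs than in tRF totals, and depth was not varied alone. Except where the number tested is given, the cause of the changes below was not tested.

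A fold of at least 2 as well, chosen after seeing the data, left fewer tRF totals: 95 of 174 in reproductive against vegetative tissue, 147 of 224 in root against shoot, 89 of 208 in panicle, 18 of 137 and 39 of 151 (36 higher, 3 lower) for cold in shoot and root, 68 of 168 and 47 of 154 for salt, and 70 of 164 and 81 of 172 for the interactions with cold and salt. Of tRNAs it left 47 of 86 in cold root, 40 of 65 in salt shoot and 28 of 66 in salt root. With this fold in the same direction, cold and salt shared 15 totals in shoot (100 without it) and 2 in root (81). After rescaling and without this fold, they shared 98 and 67. After rescaling, 59 tRNAs were called in reproductive tissue (25 higher, 34 lower), against 124 without it (107 and 17). In panicle 80 were called (41 higher, 39 lower), against 149 (148 and 1). The rescaled calls are thus not a subset of the main ones. A model of 2 groups called 35 tRNAs and 66 tRF totals in reproductive tissue, against 124 and 174. With an estimated correlation, 47 lists were called, against 84.

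Counts of individual tRFs moved under several settings. Grouped by anticodon, origin and class, fewer features were tested: 242 of 281 differed among Arabidopsis tissues, and of 266 in rice 201 differed between root and shoot, 106 and 107 for cold in shoot and root, and 141 and 106 for salt. With a mean of at least 10 RPM (806 tested), 606 differed between root and shoot and 476 for salt in shoot. With only the compared libraries, calls were 467 for cold in root, 395 for salt in shoot and 531 for salt in root, and with voom on recovered reads, chosen after seeing the data, 490, 563 and 465, against 262, 873 and 296. With a library left out, calls ranged from 1248 to 2011 among Arabidopsis tissues (1931 with all, and 1248 or 1273 without flower replicate 1 or 2), from 261 to 333 for cold in shoot (422; 261 without control 1, 265 without cold 1), from 127 to 182 for cold in root (262; 154 without control 1, 127 or 133 without cold 1 or 2), from 574 to 984 for salt in shoot (873; 574 without control 1) and from 166 to 195 for salt in root (296; lower without any of the 4 libraries).

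Among rice shares (root minus shoot, percentage points, unadjusted exact permutation p), that of mitochondrial tRNAs was 0.0723 with organelle-like copies counted as organelle (p = 0.377). With a library left out, that of mitochondrial tRFs was 0.576 to 0.8898 (exact permutation p = 0.0108 to 0.0866, under 0.05 for 5 of 12 libraries), and 5'-halves -4.804 to -3.21 (p = 0.0281 to 0.0974, under 0.05 for 6 of 12). The exact permutation test gave, without the most abundant tRNA, -3.84 for 5'-halves (p = 0.0584), -1.30 for tRF-5 (p = 0.481, against 0.0154 points) and 1.83 for 28 nt and longer (p = 0.255). For fragments without mismatches the exact permutation test gave -0.319 for 5'-halves (p = 0.805), 5.51 for tRF-5 (p = 0.0173) and -0.214 for 15 to 17 nt (p = 0.279). Fragments of 28 nt and longer were -1.14 to 0.462 with a library left out. The settings without mismatches and with organelle-like copies were chosen after seeing the data.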

Other observations

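The tests of even sequencing error, few gene copies, family mix, general misreading, the spread between replicate libraries, and of 3' fragments without the last A by organ were chosen only after the result was seen, as was the floor of 3 reads for the nuclear-to-plastid ratio.

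Rice root and shoot also differed in how tRNA 3' fragments ended. In control root 65.6 ± 0.0658% of the reads at the 3' end stopped before the last A of CCA, against 18.5 ± 0.214% in control shoot and 16.5 ± 0.107% in panicle (n = 2 each). In Arabidopsis this share ranged from 4.29 ± 0.0922% in rosette leaf to 21.1 ± 0.289% in stem and 21.9 ± 0.0315% in silique. Over 6 root and 6 shoot libraries of rice the means were 62.7% and 19.7% (exact permutation p = 0.00216, the smallest possible, two-sided, with libraries as independent units). Among nuclear fragments alone root was higher by 35.5 percentage points (67.1% and 31.6%, exact permutation p = 0.00216). Of 36 families, 32 were higher in every root library than in every shoot library, and the exceptions were nuclear Ser-GCT, Ala-TGC, Ser-AGA and Leu-AAG. The chance share is 0.108% if libraries are independent units.

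Fragments with an A at base 34 from the 5' end, the first anticodon base of nuclear Ala-AGC and Ser-AGA, mostly read G there. Over 15 such Arabidopsis fragments, the share of reads with G was 93.9 ± 0.414% in silique, 93.4 ± 1.61% in flower, 86.9 ± 0.935% in stem, 78.7 ± 2.13% in stem leaf and 72.8 ± 0.760% in rosette leaf (n = 2 each). By family, nuclear Ala-AGC gave 8.96 ± 0.237% of the Arabidopsis tRF signal in stem and 2.21 ± 0.0198% in rosette leaf. Plastid Asp-GTC gave 7.76 ± 0.172% in rosette leaf and 1.25 ± 0.00494% in silique. In rice, nuclear Arg-ACG gave 4.69 ± 0.0293% in control root and 1.65 ± 0.000893% in control shoot, and plastid Tyr-GTA 0.398 ± 0.00498% and 6.82 ± 0.184%. These families were not tested as shares.

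Single mismatches in the listed 3' fragments lay almost all at base 19 from the 3' end, 99.1% of the mismatch signal in Arabidopsis and 98.2% in rice. All 2794 listed rice fragments and at least 5808 of 5826 in Arabidopsis had a mean of at least 1 RPM. Rarer fragments may thus be missing from the list. An even spread of the listed mismatch signal would put 28.9 times less there (34.2 times in rice). Mismatches scattered over many sites would each be rarer and may be missing from the list, so this cannot measure even sequencing error. A difference in a few gene copies is excluded by mismatches in at least 42 families per species. The A at this base was read as T in 72.7% and as G in 26.5% of this signal in Arabidopsis (55.7% and 43.9% in rice). Nuclear fragments carried it in 77.3 ± 0.438% (rosette leaf) to 89.6 ± 0.0878% (silique) of Arabidopsis reads and plastid fragments in 0% in all 24 libraries, with a nuclear-to-plastid ratio of at least 231, although all 30 plastid tRNAs of Arabidopsis and 24 of 25 of rice have A at this base. These values are in line with misreading of a modified A during reverse transcription, as a hypothesis, and no modified base was measured directly.

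The nuclear base 19 mismatch was lower in stressed rice shoots: 76.8 ± 0.266% in control, 38.9 ± 0.0748% in cold and 37.6 ± 1.24% in salt (n = 2 each), and 70.0 ± 0.367%, 64.4 ± 0.375% and 57.8 ± 0.307% in root. A different mix of tRNA families is argued against by 27 of 28 nuclear families that were lower in all libraries of both stresses than in both control libraries (17 of 28 in root). The chance share is 6.67% if libraries are independent units. Reverse transcription that misreads every modified base less is argued against by bases 9 and 26 from the 5' end, which dropped by at most 21.7% of their control value against 49.4% and 51.1% at base 19. A lower modification, or a different survival of modified fragments, in stressed shoots might explain the drop as a hypothesis, and neither was tested. No permutation test of stress against control was run on these shares. Panicle, which had no treatment, stood at 54.8 ± 0.524%, so a share below that of control shoot was not limited to stress.

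Over all 3' fragments, base 19 mismatches were 36.0 percentage points more frequent in rice root than in shoot (55.98% and 20.01%, exact permutation p = 0.00216, the smallest possible, two-sided, with libraries as independent units). Among nuclear fragments alone the difference was 13.0 points (64.1% and 51.1%, exact permutation p = 0.147), and the controls went the other way, with 70.0% in root and 76.8% in shoot. Read counts of replicate libraries differed by more than sampling noise in every group (chi-square per degree of freedom 2.57 to 3.28 over individual tRFs). In 10 of 12 groups the most abundant fragments had a chi-square within 1.5 times that of the others.

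Among 100 of the 210 splits of the 10 Arabidopsis libraries into 4 and 6, a limma model of 2 groups called as many tRF totals as the real split (66) in 1, the real one itself, and the highest other count was 31. For the tRNA signal 3 of 100 splits, the real one included, called at least the real count of 35, and the highest other count was 75. Chance is excluded at the 5% level only if the libraries of a tissue are independent units, which is not known, and splits that divide tissues differ from the real one in this respect. By whole tissues there are only 10 splits, too few for a share under 0.05. The real values there were 124 tRNAs and 174 tRF totals, and the highest others 116 (rosette leaf and stem leaf against the rest) and 177 (stem leaf and stem against the rest).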
